A study of Caenorhabditis elegans with 6 samples.

How the data were processed

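Messenger RNA was sequenced from whole first-stage (L1) larvae of the nematode Caenorhabditis elegans in 3 genotypes with 2 libraries each, 6 libraries in all. N2 is the wild-type laboratory strain. The series design text writes VT1367 (HW3826), and the growth text gives VT1367 maIs105. HW3826 was taken here as the strain with maIs105, and how the 2 names relate is not stated further. maIs105 is a transgene array in which the col-19 promoter drives GFP. GR1395 carries mgIs49, an array that holds the mlt-10 promoter driving a short-lived GFP and a ttx-3 reporter, and 1 label spells this strain GR1935. Per the labels' protocols, starved larvae were synchronised overnight in M9 buffer and then grown at 25 °C, with harvest after 4 hours, RNA was purified from Trizol lysates, and libraries were made with the Illumina Stranded mRNA Prep kit and sequenced from both ends on a NovaSeq instrument. The labels do not say that the libraries of a genotype came from separate cultures, so every p-value measures only the spread between these libraries, which may be technical.

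The submitters' processing notes name the genome build ce11 and HISAT2 with the version 1.10.0. Their roles, the counting tool, the annotation and the use of strand in counting are not given in the sources used here. The authors deposited raw counts per gene, 1 column per library, for 20190 genes, together with a length per gene in bases. The authors also deposited log2 values for the same libraries. Recomputed from the deposited counts, each log2 value equalled log2 of the count divided by the library total, times the mean library total, plus 8, to within rounding, so the deposited log2 table holds no information beyond the counts. Library totals were between 42593688 and 54957641 counts. A floor of 3 counts corresponded to between 0.0546 and 0.0704 counts scaled by library total (CPM), a limit that covers counting error only.

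Gene names and positions came from the Ensembl release 115 annotation of WBcel235, which is the assembly behind ce11, by matching WormBase gene identifiers. A name and a position were found for 20105 of the 20190 genes, and the other 85 were used under their identifiers. Of the matched genes, 19898 were protein coding. Genes that overlap or lie antisense to each other, and families of near-identical copies such as the catalases ctl-1, ctl-2 and ctl-3, the hsp-16 pairs, F44E5.4 with F44E5.5, and the histones, are reported as uncertain, since reads could have been divided between them in counting. Reads from GFP were not analysed here.

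Differential abundance was tested with the edgeR quasi-likelihood test (edgeR 4.0.16, R 4.3.3, limma 3.58.1) on the deposited counts. The fit used trimmed-mean (TMM) scaling, edgeR's default expression filter, robust dispersion estimates and 1 coefficient per genotype, with all 6 libraries in 1 fit. The filter left 15024 genes, the fit had 3 residual degrees of freedom and a median prior of 10.5, and the median biological coefficient of variation was 8.25%. TMM factors were between 0.977 and 1.034. Fold changes are given as log2 with standard errors from the fit, and adjusted p-values follow Benjamini and Hochberg over all genes tested, with a threshold of 0.05 and no fold cutoff. The comparisons were HW3826 against N2, GR1395 against N2 and HW3826 against GR1395, and the overlap of the calls of both strains against N2. Per-gene levels are CPM, as mean ± SD of 2 libraries. Both array strains were compared with the same N2 libraries, so the covariance, correlation and shared sign of the fold changes are set beside 50 simulated data sets in which unchanged groups were compared with shared controls. The overlap is set beside that of independent lists, which leaves the shared controls out. With 2 N2 libraries, the controls could not be split.

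Gene lists were tested with camera in limma on log CPM values with a prior count of 2 and a preset correlation of 0.01 between genes, adjusted over the 108 tests of 36 lists and 3 comparisons. Counts of called members are also given adjusted over the list alone. Camera with an estimated correlation and fry were run beside it. With an estimated correlation no list passed: the lowest adjusted p of the 108 tests was 0.662. Fry, which asks whether the genes of a list move on balance 1 way without comparing them with other genes, passed 13 tests. Of these 13, 9 were among the 29 tests that passed camera. Among the tests that passed camera, the list's median, mean and test direction had the same sign. Chromosome shares were tested with 2-sided Fisher exact tests, adjusted over 18 tests, and neighbouring calls within 100 kb were counted against 10000 random draws of as many tested genes.

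The named genes were chosen by a fixed rule. It took the members of the lists of transgene source genes and of myrf genes, and, for each strain against N2, the 10 largest rises and 10 largest falls among genes past the threshold with a mean of at least 2 CPM and no overlap between the libraries of the groups (5 and 5 for HW3826 against GR1395). It also took up to 3 called members of each gene list with the smallest adjusted p, and the 5 genes per direction shared by both strains with the smallest larger adjusted p. Further called members named in the account of a list, the smg-2 gene and the genes of the block on chromosome IV were chosen after their values were seen. The groups, tests, gene lists, naming rule and alternatives were fixed before the data were examined, except where the closing section says otherwise. The list of transgene source genes, with 2 tested members, was too small for a list test, and the list of ribosomal RNAs had no member in the count table. For HW3826, the test found 60.0% of genes simulated to change by 0.6 on the log2 scale, 74.6% of those at 1 and 92.2% of those at 2, with 12.4% of calls false, in simulated data of 14849 genes. For GR1395 the shares found were 53.8%, 85.1% and 95.5%, with 8.2% of calls false.

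The alternatives were DESeq2 size factors and upper-quartile factors in the edgeR fit, the DESeq2 Wald test (DESeq2 1.42.0), limma-voom, no expression filter, a stricter filter, the replicate number as a block, a fit of only the groups compared, a 2-fold cutoff, limma on the deposited log2 values, and leaving out each library in turn. Leaving 1 library out leaves a group with a lone library, which is then assumed to vary like the other groups. Tables and figures were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.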

Results

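Messenger RNA of whole C. elegans larvae in the first larval stage was counted per gene in 6 libraries, 2 for each of 3 strains: wild-type N2, HW3826 with the col-19 reporter array maIs105, and GR1395 with the mlt-10 and ttx-3 reporter array mgIs49. The larvae were harvested after 4 hours at 25 °C. Developmental progress was not examined here. With 1 harvest time, a difference in progress between the strains cannot be told apart from other differences between them. The N2 libraries held 42593688 and 45867714 counts, the HW3826 libraries 53362541 and 47736810, and the GR1395 libraries 54957641 and 47259839. The translation factor gene eef-1A.1 was the most abundant gene in all 6 libraries, with 1.2% to 1.34% of the counts, and the 10 most abundant genes together took 6.05% to 6.59%. In a principal component analysis the first axis held 51.4% of the variance and set both GR1395 libraries, at 47.1 and 32, apart from the other 4, which lay between -27.9 and -11.5. The second axis held 21.6% and set HW3826, at -21.6 and -24.4, apart from N2, at 22 and 23. Within a strain, log CPM correlated across genes at 0.992 (N2), 0.994 (HW3826) and 0.993 (GR1395), and genes are not independent replicates. N2 replicate 2 carried a trend with transcript length: relative to the mean of all libraries, its median log2 value was -0.163 in the class of longest genes (median 3909 bases) and 0.125 in the class of shortest genes (median 441 bases).

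Of 15024 genes tested, 902 passed in HW3826 against N2, 532 higher and 370 lower, with 2416 in GR1395 against N2, 1192 higher and 1224 lower. HW3826 against GR1395 gave 2179 genes, 1102 higher and 1077 lower in HW3826. This balance depended on the processing. More genes were lower with limma on the deposited log2 values (868 higher and 1221 lower), upper-quartile factors (1022 and 1194), a stricter expression filter (939 and 985) or without GR1395 replicate 2 (729 and 777). Removal of the length trend gave 1476 higher and 1151 lower. Most changes were small: the median absolute log2 fold change of the called genes was 0.51, 0.49 and 0.57 in the 3 comparisons, and 150, 528 and 552 of them reached 2-fold.

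**Figure D1:**
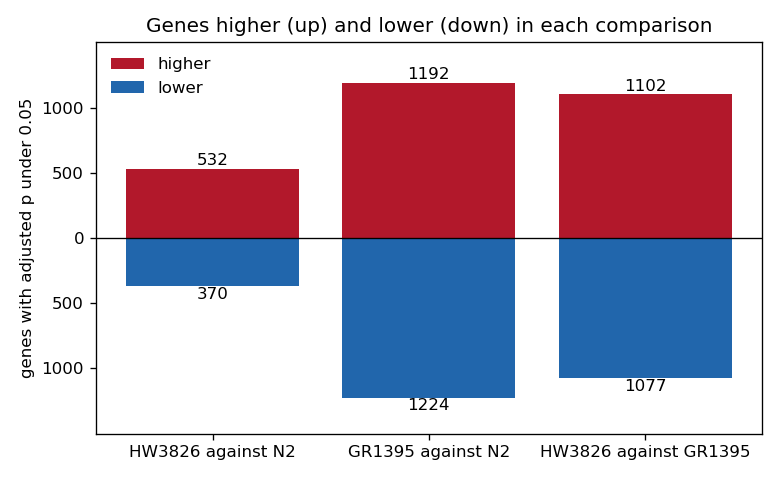
The plot counts genes past the adjusted p threshold in each comparison (n = 2 libraries per strain), higher and lower separately. GR1395 against N2 had 1192 higher and 1224 lower genes, HW3826 against N2 had 532 and 370.

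The arrays were built from the promoters of col-19, mlt-10 and ttx-3, and the series asks how such arrays modify a phenotype of myrf-1, which codes for a membrane-bound transcription factor needed for the rewiring of larval neurons and for larval development. None of the endogenous source genes passed in a strain that carries its promoter, against N2. The adult collagen gene col-19 (X 421707 to 422691) had 0 and 0 counts in N2, 1 and 0 in HW3826 and 2 and 0 in GR1395, too few for a test. mlt-10 (II 546705 to 552032), a molting gene, had log2 fold changes of 0.43 in HW3826 (adjusted p = 0.162) and -0.21 in GR1395 (adjusted p = 0.411), and the neuronal regulator ttx-3 had -0.21 and -0.08 (adjusted p = 0.662 and 0.837). Direct comparison of the array strains put mlt-10 higher in HW3826 by 0.64 (SE 0.16, adjusted p = 0.0214). That call ended without HW3826 replicate 1 or 2 or GR1395 replicate 1, with adjusted p of up to 0.169. myrf-1 (II 10496987 to 10502541) was at 124 ± 9.87 CPM (mean ± SD, n = 2) in N2, 156 ± 13.2 in HW3826 and 121 ± 14.7 in GR1395. Its log2 fold change was 0.33 in HW3826 (SE 0.10, adjusted p = 0.0712) and -0.04 in GR1395 (adjusted p = 0.832), and it was higher in HW3826 than in GR1395 by 0.37 (SE 0.10, adjusted p = 0.0253). The latter call was lost without HW3826 replicate 2 or GR1395 replicate 1 (adjusted p up to 0.239). The paralog myrf-2 and pan-1, which codes for a binding partner of both proteins, passed in no comparison, with log2 fold changes of 0.02 and -0.05 in HW3826 and 0.23 and 0.01 in GR1395, both against N2. As a list, the 3 genes passed no test, at adjusted p of 0.626, 0.821 and 0.944 in the 3 comparisons.

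HW3826 larvae, compared with N2 to show what differs in the strain with maIs105, had more transcript of several genes for fatty acid use and synthesis and almost none of 2 other genes. acs-2, an acyl-CoA synthetase of fatty acid oxidation (V 15567394 to 15569897), rose 3.25-fold from 89.2 ± 4.89 to 289 ± 25.2 CPM (log2 1.70, SE 0.09, adjusted p = 1.32e-07, n = 2 libraries per strain, edgeR). elo-5, an elongase of branched-chain fatty acids on IV, rose 1.99-fold from 150 ± 7.16 to 300 ± 33.1 CPM (adjusted p = 4.32e-05), and haf-3, a half-molecule ABC transporter (V 15760455 to 15766172), rose by 1.84 from 58.2 ± 1.03 to 208 ± 1.63 CPM (SE 0.07, adjusted p = 3.95e-09). The catalase gene ctl-1 (II 14303568 to 14306260) fell by 5.41 from 18.8 ± 0.23 to 0.441 ± 0.0304 CPM (SE 0.15, adjusted p = 6.01e-11). srw-85, a predicted chemoreceptor gene (V 19429387 to 19431136), fell by 5.56 from 73.4 ± 2.68 to 1.56 ± 0.291 CPM (SE 0.14, adjusted p = 4.05e-11). ctl-3, next to ctl-1, fell by 2.33 (SE 0.20), while ctl-2 on their other side had a log2 fold change of 0.14 (adjusted p = 0.38). The 3 catalases are near-identical copies, so the division of reads among them is uncertain. Other large falls were those of C10G8.8 (-2.86), haf-6 (-2.43), the purine synthesis gene atic-1 (-1.98), the lectin gene clec-10 (-1.78) and cyp-37B1 (-1.77). The aspartyl protease gene asp-12 rose by 2.45 (SE 0.20, adjusted p = 0.000301), piit-1 by 2.07 and the nuclear receptor gene nhr-74 by 1.67. F18E3.13, among the 10 largest rises at 1.78, lost its call without either N2 library, with an adjusted p of up to 0.184.

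Of 27 genes for fasting and fat metabolism, 10 rose and 1 fell in HW3826 (10 and 2 adjusted over the list alone), and the list was shifted upwards at adjusted p = 0.000342. With an estimated correlation the test gave adjusted p = 0.662. Besides acs-2 and elo-5, the risers were the desaturase genes fat-5 (1.79) and fat-6 (0.64), the elongase genes elo-6 (0.82) and elo-2 (0.60), hacd-1 (1.38), acdh-2 (1.08), the acetyl-CoA carboxylase gene pod-2 (0.70) and the fatty acid synthase gene fasn-1 (0.32), and the lipase gene lipl-2 fell by 0.86. Without N2 replicate 2, 6 of the 27 were called higher, with hacd-1 and elo-6 no longer among them (adjusted p = 0.0572 and 0.0569). Without N2 replicate 1, 2 were lower. acdh-2 lost its call without either N2 library (adjusted p up to 0.339), and fasn-1 in every leave-out but that of N2 replicate 1 (up to 0.387). The 34 molting and apical matrix genes were also shifted upwards (adjusted p = 0.00382, adjusted p = 0.704 with an estimated correlation), with 3 higher and 2 lower (7 and 2 adjusted over the list alone). sym-1 and noah-1, parts of the matrix over the epidermis, rose by 0.44 and 0.45, but noah-1 lost its call without either HW3826 library (adjusted p up to 0.0798) and sym-1 without N2 replicate 1 or HW3826 replicate 2 (up to 0.253). Without either HW3826 library, 1 of the 34 was higher and 1 lower, and 1 was lower in each of the other leave-outs. Of the cuticle collagens, 7 rose, 2 fell and 106 did not pass (8 and 2 adjusted over the list alone; adjusted p = 0.0083, adjusted p = 0.784 with an estimated correlation), with col-77 rising by 1.51. Without HW3826 replicate 1 no collagen was called lower, and 1 was without HW3826 replicate 2 or N2 replicate 2. The catalases counted in the list of glutathione transferases and redox genes, in which 4 of 57 fell and gst-4 rose by 0.46 (no call without HW3826 replicate 1, adjusted p = 0.0908), at an adjusted p of 0.956 for the list, whose median was 0.06, mean -0.12 and test direction down. Without N2 replicate 2, 2 genes of the list were lower.

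Calls in some further lists changed when the length trend was removed. The 81 ribosomal protein genes, whose transcripts are short, were shifted downwards by a median of -0.13 (adjusted p = 2.19e-06, adjusted p = 0.826 with an estimated correlation). Of these, 2 fell (2 adjusted over the list alone), rpl-37 (-0.43) and rps-29 (-0.35), against 23 without N2 replicate 1, 0 without HW3826 replicate 2 and 1 without HW3826 replicate 1 or N2 replicate 2 or with the length trend removed. Body wall muscle genes, some of them long, were shifted upwards (camera adjusted p = 0.0161, adjusted p = 0.662 with an estimated correlation). Of 17, 3 rose (4 adjusted over the list alone): unc-22 (0.44), ttn-1 (0.43) and unc-89 (0.34). With the length trend removed 0 of the 17 passed, ttn-1 had -0.13 and unc-89 -0.08, and 0 passed without either HW3826 library, and 1 passed without N2 replicate 2; unc-89 also lost its call without either GR1395 library (adjusted p up to 0.215).

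The heterochronic genes puf-9 (0.36), daf-12 (0.45) and hbl-1 (0.41) rose, 3 of 19 (4 adjusted over the list alone; adjusted p = 0.0328, adjusted p = 0.784 with an estimated correlation), and with the length trend removed 3 of the 19 passed, hbl-1 not among them (adjusted p = 0.0884). No heterochronic gene passed without N2 replicate 2 or either HW3826 library, and 7 did without N2 replicate 1. hbl-1 also lost its call without either GR1395 library (adjusted p up to 0.214). Of 251 genes of the F-box, MATH and BTB families, 10 fell and 1 rose (4 and 0 adjusted over the list alone; adjusted p = 0.0244, adjusted p = 0.662 with an estimated correlation). Of the 251, 6 were lower without N2 replicate 2 or either HW3826 library, 5 without N2 replicate 1 and 8 with the length trend removed. Germline genes were shifted upwards by a median of 0.12 (adjusted p = 0.032, adjusted p = 0.784 with an estimated correlation), although edgeR called 0 of 29 (0 adjusted over the list alone), with 6 higher and 2 lower at an unadjusted p under 0.05, and DESeq2 and limma-voom called 0. 1 was called without N2 replicate 1.

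A block of 6 neighbouring genes on IV (3584400 to 3609229) was higher in HW3826 against N2. The transcription initiation factor gene taf-2 rose by 1.27, Y37E11B.5 by 0.91, Y37E11B.6 by 0.58 and the kinase gene kgb-2 by 0.77, with Y37E11B.7 between them in size. The call of Y37E11B.6 ended without N2 replicate 1 or either HW3826 library (adjusted p up to 0.201) and that of kgb-2 without HW3826 replicate 2 (0.0758). Y37E11B.10 rose by 6.21 (SE 0.34, adjusted p = 1.21e-07), from 2 and 5 counts in N2 to 300 and 309 in HW3826, so the size of this rise is limited by the N2 counts. The flanking genes blos-7 (0.09) and ltah-1.2 (0.11) did not pass, and kgb-2 overlaps ltah-1.2, which leaves the division of their reads uncertain.  The block was chosen after its values were seen.

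**Figure D2:**
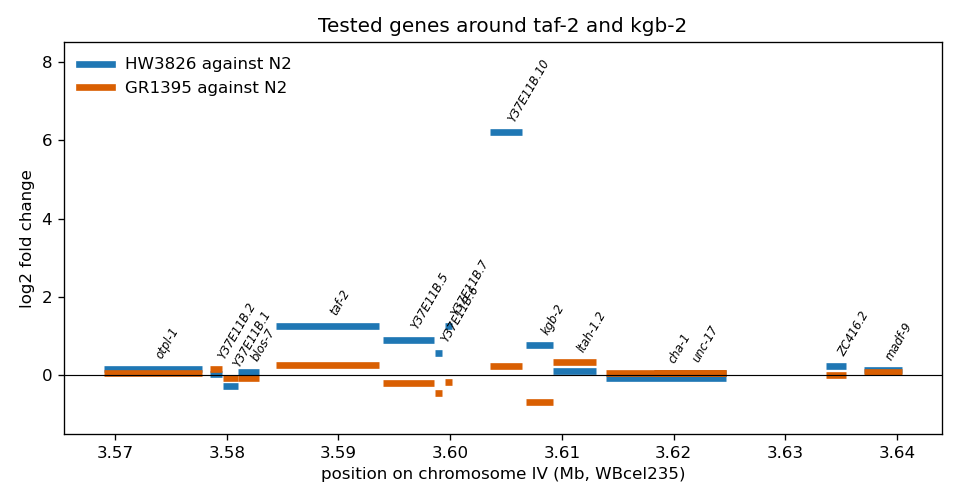
Each bar is a gene of the region on chromosome IV from its start to its end (x axis, position in Mb), at its log2 fold change against N2 (y axis) in HW3826 and in GR1395, from 2 libraries per strain. In HW3826 the 6 genes from 3584400 to 3609229 lay between 0.58 and 6.21.

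The HW3826 count against N2 depended on single libraries: it was 489 without HW3826 replicate 1 and 378 without replicate 2.

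GR1395 larvae, compared with N2 to show what differs in the strain with mgIs49, had more transcript of several heat shock and glutathione transferase genes and less of several maternal, cell cycle and apical matrix genes. aex-5, a proprotein convertase gene expressed in the intestine (I 14850052 to 14855827), rose 4.24-fold from 27.9 and 29.7 CPM in the N2 libraries to 123 and 121 in those of GR1395 (log2 2.08, SE 0.08, adjusted p = 2.7e-09, n = 2 libraries per strain, edgeR). The glutathione transferase genes gst-1 and gst-4 rose 2.14-fold (114 ± 13.6 to 244 ± 1.8 CPM, adjusted p = 1.63e-05) and 2.22-fold (adjusted p = 2.96e-05), and the chaperone gene hsp-70 rose by 1.23 (SE 0.18, adjusted p = 0.00102). The maternal oocyte maturation gene oma-1 fell by 2.18 from 8.89 ± 0.659 to 1.99 ± 0.693 CPM (SE 0.21, adjusted p = 0.000129), the cyclin B gene cyb-1 by 1.13 (SE 0.14, adjusted p = 0.000932) and noah-1 by 0.95 (SE 0.10, adjusted p = 0.000104). srw-85 fell by 5.01 (SE 0.13, adjusted p = 7.92e-11) and haf-6 by 2.61 (SE 0.10), as they did in HW3826. Among the 10 largest rises, W06H8.2 (2.28), M60.7 (2.16) and aex-5 passed in each of the 6 leave-outs. The rises of fmo-2 (2.57), Y40B10B.1 (2.29) and irg-5 (2.03) lost their call without either N2 or either HW3826 library (adjusted p up to 0.204, 0.182 and 0.267), and T21C9.9 (2.09) also without GR1395 replicate 1 (up to 0.261). F47B8.10 (2.24) lost its call without either N2 library (up to 0.131), and R12G8.1 (2.12) without N2 replicate 2 (0.0697). irg-5 was at 47.3 and 23.4 CPM in the 2 GR1395 libraries and fmo-2 at 33.3 and 16.9. Of the 10 largest falls, 9 were those of F14H3.6 (-3.65), meg-1 (-3.54), C17E7.4 (-3.52), ZC308.4 (-3.17), era-1 (-3.12), pos-1 (-3.10), sepa-1 (-3.05), F14D7.2 (-3.03) and vet-1 (-2.98), several of which are maternal or early embryonic genes. Each of the 9 ended its call without N2 replicate 2, and all but era-1 also did so without HW3826 replicate 2, with adjusted p between 0.062 and 0.218 at the highest. Further libraries whose removal ended such a call were N2 replicate 1 for F14H3.6, meg-1, C17E7.4 and pos-1, HW3826 replicate 1 for all but era-1 and vet-1, and GR1395 replicate 1 for F14H3.6 and sepa-1.

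Of 11 genes of the cytosolic heat shock response, 9 rose and 0 fell in GR1395 (9 and 0 adjusted over the list alone; adjusted p = 2.75e-05, adjusted p = 0.662 with an estimated correlation). Of the names planned for this list, 5 had no match in the count table, among them hsp-16.1, hsp-16.11, hsp-16.48 and hsp-16.49. The median log2 fold change of the 11 genes was 1.23. hsp-16.2 was at 2.17 and F44E5.5 at 1.72, each with a near-identical copy that leaves the single gene uncertain. Without N2 replicate 2, 2 of them passed, hsp-16.2 not among them (adjusted p = 0.0846), and 5 did without GR1395 replicate 1. Glutathione transferases and redox genes rose in 19 cases and fell in 4 of 57 (22 and 6 adjusted over the list alone; adjusted p = 0.00655, adjusted p = 0.784 with an estimated correlation), with gst-12 at 1.37. Without GR1395 replicate 1, 6 were higher and 1 lower, and 2 were lower without GR1395 replicate 2 or N2 replicate 2.

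Germline genes fell in 8 of 29 cases and 1, the Argonaute gene csr-1 (0.36), rose (9 and 1 adjusted over the list alone; adjusted p = 0.0021, adjusted p = 0.784 with an estimated correlation). The fallers included the P granule and maternal genes meg-2 (-2.46), oma-1 and oma-2 (-1.28) and the chromatin gene mes-4 (-0.51), whose call ended without GR1395 replicate 1 (adjusted p = 0.0539). 4 were lower without N2 replicate 2 and 5 without GR1395 replicate 1, 2 were higher without N2 replicate 1, and csr-1 lost its call without N2 replicate 2 or either GR1395 library (adjusted p up to 0.2). DNA replication and cell cycle genes fell in 9 of 24 cases, cyb-1 among them, while the cell cycle inhibitor gene cki-1 rose by 0.49 (13 and 1 adjusted over the list alone; adjusted p = 0.000343, adjusted p = 0.784 with an estimated correlation). Without N2 replicate 2 or GR1395 replicate 1, 2 were lower. The histones fell in 4 of 21 cases (4 adjusted over the list alone; adjusted p = 0.0484, adjusted p = 0.784 with an estimated correlation), none without N2 replicate 2 or GR1395 replicate 1, and their near-identical copies are uncertain.

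Among the lists with more called genes lower than higher in GR1395 were molting and apical matrix genes, cuticle collagens, C-type lectins and intestine genes. The molting and collagen lists did not pass camera. Of 34 molting and apical matrix genes, 11 fell and 3 rose (12 and 6 adjusted over the list alone), with noah-2 at -1.40, the protease inhibitor gene mlt-11 at -1.40, lpr-3 at -1.39 and sym-1 at -1.29, and the list had an adjusted p of 0.0989. 7 were higher without N2 replicate 1, 0 without N2 replicate 2 or GR1395 replicate 2, and 1 without GR1395 replicate 1. Of the cuticle collagens, 24 fell, col-147 by 0.85, 6 rose and 85 did not pass (26 and 6 adjusted over the list alone), at an adjusted p of 0.0533. 11 were lower and 1 higher without GR1395 replicate 1, 13 lower without N2 replicate 2, and 4 higher without N2 replicate 1. C-type lectin genes fell in 25 of 125 cases and rose in 8 (31 and 10 adjusted over the list alone; adjusted p = 0.0118, adjusted p = 0.662 with an estimated correlation), with clec-61 at -1.92 and clec-86 at -1.85. Without GR1395 replicate 1, 2 were higher, and without N2 replicate 2, 5 were. Intestinal genes fell in 6 of 19 cases and rose in 2 (7 and 2 adjusted over the list alone; adjusted p = 0.0328, adjusted p = 0.662 with an estimated correlation), with the metallothionein gene mtl-2 lower 1.99-fold (adjusted p = 9.56e-05). Without GR1395 replicate 1, 1 was lower and 0 higher, and 1 was higher without GR1395 replicate 2 or N2 replicate 2.

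Ribosomal protein genes were shifted downwards by a median of -0.21 (adjusted p = 1.18e-09, adjusted p = 0.784 with an estimated correlation) and 7 of 81 fell (4 adjusted over the list alone), rpl-37 by 0.56. This count was 66 without N2 replicate 1, 3 without N2 replicate 2, 4 without either HW3826 library, 2 without GR1395 replicate 1, 1 without GR1395 replicate 2 and 2 with the length trend removed. Neuronal genes, many of them long, were shifted upwards, and 5 of 22 rose, among them the active zone gene cla-1 (0.55) (5 adjusted over the list alone; adjusted p = 0.032, adjusted p = 0.662 with an estimated correlation). Of these 22, 0 passed without GR1395 replicate 1, 2 without GR1395 replicate 2, 1 without N2 replicate 2 and 1 with the length trend removed. Of 19 heterochronic genes, 3 rose, nhl-2 (0.57) and puf-9 (0.40) among them, and lin-42 fell by 0.54 (9 and 1 adjusted over the list alone; adjusted p = 0.0172, adjusted p = 0.784 with an estimated correlation). Without N2 replicate 1, 11 rose, without GR1395 replicate 1, 1 rose and 0 fell, and without N2 replicate 2, 0 fell. With the length trend removed, 3 rose and 1 fell. puf-9 lost its call without GR1395 replicate 1 (adjusted p = 0.054), and lin-42 without that library or N2 replicate 2 (up to 0.192).

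**Figure D3:**
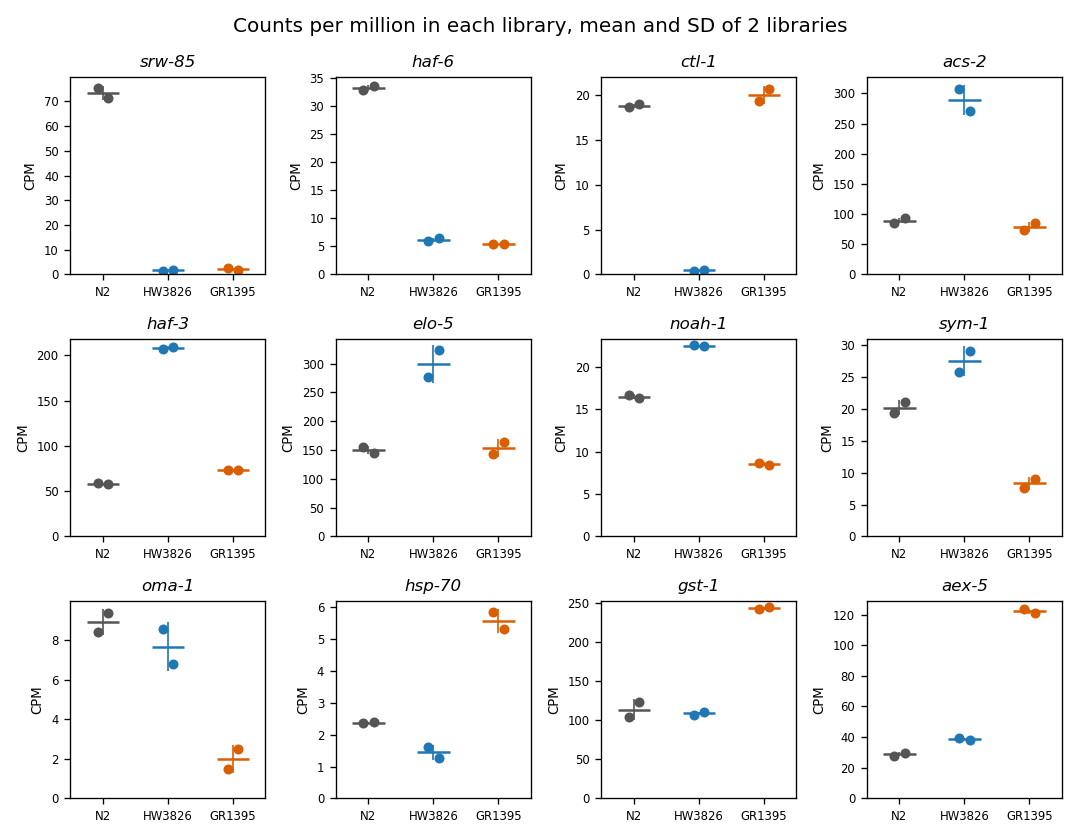
Dots are single libraries (2 per strain), lines their means and vertical bars the SD, in CPM on the y axis, for 12 genes. srw-85 and haf-6 were lower in both array strains, ctl-1 in HW3826 alone of the 3, and oma-1 and noah-1 were lowest in GR1395.

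The whole GR1395 count against N2 was 928 without N2 replicate 2, 656 without GR1395 replicate 1 and 1527 without GR1395 replicate 2. In limma on the deposited log2 values, 1446 were higher and 927 lower.

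HW3826 and GR1395, both with an array, were also compared directly. ctl-1 was lower in HW3826 by 5.50 on the log2 scale (log2 -5.50, SE 0.15) and Y37E11B.10 higher by 5.96 (SE 0.32), with 5 and 5 counts in GR1395. acs-2 was higher in HW3826 by 1.87 (SE 0.09, adjusted p = 7.12e-08), elo-6 by 1.01 (SE 0.11) and elo-5 by 0.96. The matrix genes sym-1 (1.73, SE 0.11), noah-2 (1.67, SE 0.14) and noah-1 (1.40, SE 0.10, adjusted p = 1.33e-06) and the collagen gene col-77 (2.76, SE 0.26) were higher in HW3826. The chaperone gene hsp-70 (-1.94, SE 0.19), gst-1 (-1.16, SE 0.09) and M60.7 (-3.03, SE 0.26) were lower in HW3826. Of the 5 largest differences in each direction, those of F14H3.6 (3.37), C17E7.4 (3.34), meg-1 (3.33) and ZC308.4 (2.83) lost their call without any 1 of the N2 or HW3826 libraries, F14H3.6 also without GR1395 replicate 1 (adjusted p up to 0.304), and that of sod-5 (-3.56) without HW3826 replicate 2 (0.0647).

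Germline genes were higher in HW3826 in 10 of 29 cases and lower in 0 (16 and 0 adjusted over the list alone; adjusted p = 9.4e-07, adjusted p = 0.662 with an estimated correlation), with oma-1 at 1.96, meg-2 at 1.82 and the translational repressor gene gld-1 at 0.69. Without either HW3826 library, 6 were higher. Cuticle collagens were higher in 35 cases and lower in 3, and 77 did not pass (42 and 7 adjusted over the list alone; adjusted p = 0.000342, adjusted p = 0.719 with an estimated correlation). 21 were higher and 1 lower without GR1395 replicate 1, 23 and 1 without HW3826 replicate 1, and 1 was lower without GR1395 replicate 2 or HW3826 replicate 2, but 6 without either N2 library. The furrow collagens dpy-10 (0.84) and dpy-2 (0.63), 2 of 6, were higher (5 adjusted over the list alone; adjusted p = 0.0102, adjusted p = 0.662 with an estimated correlation), 0 without HW3826 replicate 1 or GR1395 replicate 1 and 1 without HW3826 replicate 2. dpy-2 lost its call without any 1 of the HW3826 or GR1395 libraries (adjusted p up to 0.158) and dpy-10 without HW3826 replicate 1 or GR1395 replicate 1 (up to 0.0634). Against N2, edgeR called 0 of the 6 in either strain, with 1 higher in HW3826 and 2 lower in GR1395 at an unadjusted p under 0.05, and DESeq2 and limma-voom called 0. Molting and apical matrix genes were higher in 13 of 34 cases and lower in 2 (15 and 2 adjusted over the list alone; adjusted p = 0.00137, adjusted p = 0.662 with an estimated correlation), and 1 was lower without GR1395 replicate 1 or HW3826 replicate 2.

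Heat shock genes were lower in HW3826 in 6 of 11 cases (7 adjusted over the list alone; adjusted p = 0.000414, adjusted p = 0.662 with an estimated correlation). The redox list was lower in 18 of 57 cases and higher in 3 (23 and 5 adjusted over the list alone; adjusted p = 0.00137, adjusted p = 0.784 with an estimated correlation), with 5 higher without either N2 library. Fat metabolism genes were higher in 10 of 27 cases and lower in 3 (11 and 3 adjusted over the list alone; adjusted p = 0.00319, adjusted p = 0.662 with an estimated correlation), with 1 lower without GR1395 replicate 2 or HW3826 replicate 2. Intestinal genes were higher in 8 of 19 cases and lower in 1 (9 and 2 adjusted over the list alone; adjusted p = 0.00675, adjusted p = 0.662 with an estimated correlation), with 4 higher without HW3826 replicate 1 and 3 lower without either N2 library. cyb-1 (0.86) and cyb-3 (0.99) were higher and cki-1 lower (-0.61) among 24 cell cycle genes (2 and 1 adjusted over the list alone; adjusted p = 0.0113, adjusted p = 0.784 with an estimated correlation), where 1 was higher without GR1395 replicate 1 or either HW3826 library and 4 without either N2 library. The call of cyb-3 ended in each leave-out except that of GR1395 replicate 2 (adjusted p up to 0.174). F-box, MATH and BTB genes were lower in 37 of 251 cases and higher in 16 (48 and 25 adjusted over the list alone; adjusted p = 0.0404, adjusted p = 0.662 with an estimated correlation). 12 were lower and 3 higher without GR1395 replicate 1, 17 and 7 without HW3826 replicate 1, 21 and 11 without HW3826 replicate 2, and 10 were higher without GR1395 replicate 2. Ribosomal protein genes had a median of 0.07 (adjusted p = 0.0405, adjusted p = 0.936 with an estimated correlation), and edgeR and limma-voom called 0 of 81 (0 adjusted over the list alone), DESeq2 called 1, and 1 was higher at an unadjusted p under 0.05. The whole count fell from 2179 to 745 without GR1395 replicate 1, 1011 without HW3826 replicate 1 and 1207 without HW3826 replicate 2.

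The strains shared 350 genes that changed the same way against N2, 229 higher and 121 lower, where independent lists would share 42.2 and 30.1. In opposite directions, 24 changed, where 72.7 would. haf-6, a half-molecule ABC transporter gene needed for RNA interference in some tissues (I 1162880 to 1175809), stood at 33.1 ± 0.556 CPM in N2, 6.14 ± 0.381 in HW3826 and 5.42 ± 0.022 in GR1395. Its neighbour smg-2, for decay of aberrant transcripts, was higher in both, by 0.44 (no call without HW3826 replicate 1, adjusted p = 0.0696) and 0.54. The overlap of haf-6 with Y48G8AL.7 leaves part of its reads uncertain. srw-85 and the lectin genes clec-61 (-3.24 and -1.92) and clec-86 (-1.43 and -1.85) were lower in both, as was dhs-21, for sugar metabolism (-0.91 and -0.73). Among the genes higher in both were R07B1.8 (1.94 and 1.62), tag-293 (0.84 and 0.92), oac-46 (0.74 and 0.75), F17A9.4 (0.64 and 0.91) and pod-2 (0.70 and 0.53). Both strains were compared with the same N2 libraries. In 50 simulations of unchanged groups with shared controls, the covariance of the log2 fold changes was 0.0309, against 0.0828 observed, a difference of 0.0519. The simulations gave a gene the same dispersion in all strains. The N2 libraries differed more from each other, by a median absolute log2 value of 0.158, against 0.118 in HW3826 and 0.119 in GR1395. The simulated covariance may thus be too low and the difference too large. Unchanged groups give almost no calls, so these simulations do not measure what shared controls add to the overlap. Over all tested genes, the share with the same sign was 64.9%, below the 65.8% to 67.7% of the simulations. The correlation of the log2 fold changes across genes was 0.355, below their 0.479 to 0.546. The controls cannot be split, so part of the excess may come from the shared controls. The shared higher genes were long, with a median of 2399 bases against 1290 for all tested genes, and the shared lower genes had 1112. With the length trend removed, 143 of the 229 higher genes (62.4%) and 102 of the 121 lower genes (84.3%) were still called, and 163 shared genes were higher and 137 lower. The overlap of 350 was 744 without N2 replicate 1, 162 without N2 replicate 2, 207 and 173 without HW3826 replicate 1 or 2, and 141 without GR1395 replicate 1.

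The tests of chromosome shares treat genes as independent, which they are not, so their p-values may be too small. Called genes were spread unevenly over the chromosomes in HW3826. Against N2, 7.85% of tested genes on V were called and 5.49% elsewhere (adjusted p = 1.9e-05, 2-sided Fisher exact test), and at 2-fold 1.99% and 0.723% (adjusted p = 1.9e-08). acs-2, haf-3, asp-12, fat-5, srw-85 and C10G8.8 lie on V. Fewer were called on III (4.04% against 6.35%, adjusted p = 5.92e-05) and I (4.85% against 6.21%, adjusted p = 0.0405). At 2-fold, I did not pass (0.611% against 1.07%, adjusted p = 0.0657), III passed as lower (0.396% against 1.11%, adjusted p = 0.00208), and so did X (0.446% against 1.1%, adjusted p = 0.00586). Against GR1395, V again had more calls, 555 of 3272 genes over all calls (adjusted p = 5.92e-05) and 5.5% against 3.17% at 2-fold (adjusted p = 1.9e-08). III had fewer, 12.7% against 14.8% over all calls (adjusted p = 0.0298) and 2.07% against 3.96% at 2-fold (adjusted p = 1.29e-05). I had fewer at 2-fold only (2.79% against 3.83%, adjusted p = 0.0281). GR1395 against N2 showed no chromosome past the threshold over all calls. At 2-fold, GR1395 had more calls on II (4.88% against 3.24%) and V (4.68% against 3.19%, adjusted p = 0.000271 for both) and fewer on III (1.45% against 3.88%, adjusted p = 3.5e-09) and I (2.58% against 3.68%, adjusted p = 0.0158).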

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

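The tests of germ cell number, of the shared N2 libraries, of the N2 stock, of the length trend for the genes higher in both strains, of the placement of genes changed at least 2-fold and of an added copy of the block on chromosome IV were chosen after the result was seen.

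Past the threshold against N2 in both strains, but in opposite directions, were 24 genes, each also past it between the array strains. Higher in HW3826 than in GR1395, by log2 values of HW3826 minus GR1395, were nspb-12 (4.06), K10H10.4 (3.09), col-77 (2.76), C02E7.7 (2.61), cyp-33D3 (2.46), F41F3.3 (2.34), col-130 (2.14), sym-1 (1.73), kgb-2 (1.44), noah-1 (1.40), asns-2 (1.04), spp-23 (0.99), clec-166 (0.94), ifc-1 (0.82), F26H9.5 (0.81), cyp-13A2 (0.68), tyr-2 (0.67) and acs-1 (0.66). Lower in HW3826 than in GR1395 were warf-1 (-2.60), dao-6 (-1.98), F59F5.3 (-1.42), K09F6.9 (-0.96), T10E9.1 (-0.90) and ikb-1 (-0.59). All 24 stayed past the threshold between the array strains with any 1 library left out, but none kept both calls against N2. The call in HW3826 against N2 held in all 6 leave-outs for 3 genes (asns-2, col-77 and dao-6) and was lost by 13 without N2 replicate 1, 9 without N2 replicate 2, 15 without HW3826 replicate 1, 16 without HW3826 replicate 2 and 3 without either GR1395 library. The call in GR1395 against N2 held for 6 (F26H9.5, F41F3.3, clec-166, noah-1, spp-23 and sym-1) and was lost by 3 without N2 replicate 1, 13 without N2 replicate 2, 16 without GR1395 replicate 1, 7 without GR1395 replicate 2 and 1 without either HW3826 library. So for each gene at least 1 of the calls against N2 depends on a single library. The call between the array strains does not, but the 24 were chosen for opposite changes against the same N2 libraries. A difference between the array strains followed from that choice and adds no separate support.

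Transcripts of the early embryo were lower in GR1395: 23 of 26 markers from a list written before the test could be tested, so most are also measurable in these larvae, 19 lay below 0 against N2, 9 passed as lower and 1, med-2, as higher. The most abundant of the 23, mex-3, had a log2 fold change of -0.43 (32.6 and 38.7 CPM in the GR1395 libraries), and mex-5 had -2.06 (19.4 and 22.6 CPM in N2, 4.08 and 6.07 in GR1395). The length trend is argued against, since its removal left the embryo median against N2 at -0.46. Whether GR1395 larvae had fewer germ cells stays undecided. The 11 germ cell markers, with a median of -0.06 (spread 0.07) against N2, all belong to the planned germline list. They hold its only called riser, csr-1, and none of its 8 called fallers, so their choice favoured a median near 0. For HW3826 minus GR1395 their median was 0.31 (SD across genes 0.19), and pgl-1, deps-1 and wago-1 passed, beside 0.67 for the embryo markers. Each spread here is a standard error of the median that treats genes as independent, which they are not, so it may be too small. Fewer unhatched embryos among the GR1395 larvae may account for part of the lower embryo transcripts, but the drop set beforehand as speaking for this was not reached. The embryo median of -0.47 (spread 0.19) against N2 lay on the side set as speaking against it, by less than its spread. HW3826 minus GR1395 (0.67) lay between both sides. The planned list of adult and embryo carry-over genes (13 tested, camera adjusted p = 0.566) had a median of -0.04 and a mean of -0.55 against N2. Fewer unhatched embryos thus stay undecided as an explanation. A biological difference in the clearance or amount of maternal transcripts between the strains stays open and was not tested.

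Both strains shared 350 genes changed the same way against N2, how many of these the shared N2 libraries alone would give was not measured, and since the 2 N2 libraries cannot be split, a shift of these libraries and a common difference of both strains cannot be told apart. The length trend is argued against as the whole source, since with it removed 245 of the 350 were still shared, among 300 shared genes in all. For the 229 genes higher in both it stays open: 143 of them were still called in both with the trend removed. A difference of the N2 stock or its cultures could also give such an overlap, and with 1 group without an array (N2) the design cannot tell that from an effect of carrying an array. Effects of the arrays themselves stay open as well.

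Genes changed in HW3826 lay near each other in part: 736 of the 902 called genes had another within 100 kb, which random placement gives as well (mean 756), but among genes changed at least 2-fold it was 70 of 150, against 40.7 on average and 66 at most in 10000 draws (p = 0.0001, the smallest the permutation can give). Even placement over all tested genes is thus argued against for genes changed at least 2-fold in HW3826 against N2. The draws did not keep the number of genes on each chromosome, and 65 of the 150 lay on V. Part of the excess may come from that share, and placement within chromosomes was not tested. In HW3826 against GR1395, 403 of 549 genes changed at least 2-fold had another within 100 kb, against 372 on average in the random draws (permutation p = 0.003). That is also more than random placement usually gives, though within the full range of the draws (323 to 413). These draws did not keep the number of genes on each chromosome either. An added copy of the block on IV is argued against for Y37E11B.10, whose rise of 6.21 is far above what a copy would add. For its other 5 genes, whose log2 fold changes spanned a range of 0.69 (0.58 to 1.27), an added copy may hold and stays undecided. Linked sequence variants of the HW3826 strain were not tested.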

How the results depend on the processing

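Removing the length trend and the replicate number as a crossed block were chosen after the data had been seen. Across the alternatives other than those below, the counts lay between 749 and 1160 for HW3826 against N2, 2061 and 2712 for GR1395 against N2, 1908 and 2841 for HW3826 against GR1395, and 292 and 451 for the shared genes, all within 1.5 times the reported counts. For the named genes, 3943 values under alternatives kept direction and side of the threshold, 482 lost the call, 13 gained one and 19 changed sign. The 2 libraries per strain set the limit, since a lone library left in a group is assumed to vary like the others. With 3 counts over all libraries, col-19 could not be tested. The cause of the changes below was not tested, except that a 2-fold cutoff passes fewer genes by construction.

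A 2-fold cutoff left 150, 528 and 552 genes in the 3 comparisons and 32 shared genes, and raised the chromosome tests that passed from 5 to 10. The replicate number as a block gave 594 genes for HW3826 against N2 and as a crossed block 2509. The list tests that passed went from 29 to 0 with an estimated correlation and to 13 with fry. Only 9 of the 13 were among the 29. With each library left out in turn, the counts ranged from 378 to 1191 (HW3826 against N2, lowest without HW3826 replicate 2, highest without N2 replicate 1), from 656 to 3428 (GR1395 against N2, without GR1395 replicate 1 and N2 replicate 1), from 745 to 2940 (HW3826 against GR1395, without the same libraries) and from 141 to 744 (shared genes, likewise).

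Among values that changed sign, most were near 0 and not called. Leave-outs moved mlt-10 in GR1395 against N2 between -0.54 and 0.07, ttx-3 in HW3826 against GR1395 between -0.29 and 0.02, myrf-1 in GR1395 against N2 between -0.17 and 0.08, with 0.04 without N2 replicate 1, and myrf-2 in HW3826 against N2 between -0.10 and 0.15, with -0.02 without HW3826 replicate 2. pan-1 moved between -0.18 and 0.08 in HW3826 against N2 (0.06 without HW3826 replicate 1), between -0.11 and 0.13 in GR1395 against N2 (-0.09 without GR1395 replicate 2) and between -0.18 and 0.07 in HW3826 against GR1395 (0.04 without GR1395 replicate 2). In limma on the deposited log2 values, myrf-1 in GR1395 against N2 was 0.01. With the length trend removed, myrf-2 in HW3826 against N2 was -0.13 and pan-1 in GR1395 against N2 -0.04. The same correction turned the called rises of the long genes ttn-1 (-0.13), unc-89 (-0.08) and vab-10 (-0.09) in HW3826 against N2 and of ttn-1 in GR1395 against N2 (-0.03).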

Other observations

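None of the tests in this part was added after the result was seen. Several gene groups that did not pass camera held single genes with clear changes. Cytochrome P450 and UGT genes, which modify foreign compounds, went both ways among 136 tested: 14 rose and 9 fell in HW3826 against N2, 14 rose and 14 fell in GR1395, and 20 were higher and 18 lower in HW3826 than in GR1395. ugt-53 rose in both strains, by 1.06 and 0.64, and cyp-37B1 fell by 1.77 in HW3826. These counts were 8 and 5 in HW3826 without its replicate 2, 6 and 9 in GR1395 without its replicate 1, 8 lower without its replicate 2, 5 and 7 without N2 replicate 2, and between the array strains 11 and 9 without GR1395 replicate 1, 9 lower without HW3826 replicate 1 and 11 higher without HW3826 replicate 2. Of 16 genes of the DAF-16 and L1 arrest list, 3 rose and 3 fell in HW3826, 5 rose and 3 fell in GR1395, and 5 were higher and 6 lower in HW3826 than in GR1395. With fry this list passed in HW3826 against N2 (fry adjusted p = 0.0485, camera adjusted p = 0.442), with a median of -0.07 and a mean of -0.56. It also passed in HW3826 against GR1395 (fry adjusted p = 0.0376, camera adjusted p = 0.27), with a median of -0.31 and a mean of -0.79. Its member ctl-1, at -5.41 and -5.5, weighs heavily on both means, so a shift of the list as a whole is not shown. In HW3826, 1 rose without its replicate 1 and 0 without its replicate 2, in GR1395 1 fell without its replicate 2 or N2 replicate 2 and 3 rose without its replicate 1 or N2 replicate 1, and 2 were higher between the strains without any 1 of their 4 libraries. In GR1395, the insulin-responsive regulator gene daf-16 rose by 0.68 and lea-1 by 0.52. The small RNA silencing list (43 genes) held rrf-2, an RNA-directed RNA polymerase gene, which rose by 1.22 in GR1395, where 5 rose and 1 fell, against 1 and 0 in HW3826 and 2 higher and 1 lower between the strains, and 10 rose in GR1395 without N2 replicate 1 and 1 without N2 replicate 2 or either GR1395 library. Among 55 genes of the pharyngeal cuticle families, 5 rose in HW3826, 5 rose and 6 fell in GR1395, and 7 were higher and 3 lower between the strains. abu-14 fell by 1.01 in GR1395 and passed in each of the 6 leave-outs. Without HW3826 replicate 2 none of them rose in HW3826, 1 did without HW3826 replicate 1, 2 without N2 replicate 2 and 8 without N2 replicate 1. In GR1395, 0 rose without N2 replicate 2 or GR1395 replicate 1, 2 without HW3826 replicate 2 and 8 without N2 replicate 1. Between the strains, 4 were higher without HW3826 replicate 1 or GR1395 replicate 2 and 11 without N2 replicate 1.

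Further lists are given as genes higher and lower in HW3826 against N2, in GR1395 against N2, and in HW3826 against GR1395, and single left-out libraries moved many of these small counts by more than 1.5 times. The 17 intestinal immune effectors gave 1 and 3, 1 and 4, and 2 and 3, with dod-24 lower in both strains, by log2 values of -0.69 and -0.82, and a median of 0.11 and mean of -0.15 between the strains. The 14 epidermal antimicrobial peptides gave 1 and 1, 4 and 0, and 1 and 4, with nlp-28 at -0.82 in HW3826. The 14 hypodermis and seam genes gave 3 and 0, 1 and 0, and 3 and 1, with nhr-74 at 1.67 in HW3826, and in GR1395 their median was -0.08 and their mean 0.13. The 26 insulin-like peptide genes gave 0 and 1, 1 and 3, and 2 and 2, with ins-27 at -0.96 in GR1395. The 34 genes of the intracellular pathogen response gave 0 and 0, 2 and 1, and 1 and 2. Pharyngeal muscle and gland genes (13) gave 1 and 0, 6 and 1, and 0 and 2, and AIY interneuron genes (10) gave 0 and 1, 1 and 1, and 0 and 0. Molting oscillator regulators (10) gave 1 and 0, 2 and 1, and 2 and 1. Heterochromatin and repressor genes (27) gave 2 and 0, 0 and 4, and 1 and 0, with mes-4 higher in HW3826 than in GR1395. Genes of the mitochondrial unfolded protein response (7) gave 2 and 0, 2 and 0, and 0 and 0, those of the ER response (13) 0 and 0, 1 and 0, and 1 and 0, and mitochondrially encoded genes (12) 0 and 0, 2 and 0, and 0 and 1, with medians of 0.12 and -0.27 and means of -0.05 and 0.11 in the last 2 comparisons. Glia and coelomocyte genes (7) gave 0 and 0, 0 and 0, and 0 and 1, and carry-over markers of adults and embryos (13) 1 and 0, 1 and 1, and 2 and 0, with skn-1 higher by 0.47 in GR1395. C-type lectin genes (125) gave 7 and 13 in HW3826 against N2 and 15 and 12 between the strains, and body wall muscle genes (17) 4 and 2 in GR1395 against N2 and 3 and 1 between the strains. Neither list passed camera in these comparisons, but with fry the lectins passed as lower in HW3826 (adjusted p = 0.0376) and the muscle genes as higher in HW3826 than in GR1395 (adjusted p = 0.0378). For the 6 co-transformation marker genes, which are often placed in arrays, edgeR, DESeq2 and limma-voom called 0 in all 3 comparisons, and 1 was higher in each at an unadjusted p under 0.05.

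Median, mean and test direction differed in sign in lists that did not pass camera. In HW3826 against N2, heat shock genes had a median of 0.12, a mean of -0.18 and a test direction up, AIY genes 0.01, -0.07 and down, heterochromatin genes -0.01, 0.03 and up, pharyngeal muscle and gland genes -0.02, 0.03 and up, and mitochondrially encoded genes 0.03, 0.06 and down. In GR1395 against N2, F-box, MATH and BTB genes had 0.06, -0.11 and up, pharyngeal cuticle genes 0.01, -0.10 and down, and small RNA silencing genes -0.01, 0.07 and up. Between the array strains, myrf genes and their partner had -0.06, 0.03 and up, pharyngeal muscle and gland genes 0.01, 0.00 and down, and small RNA silencing genes 0.01, -0.01 and up.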
